A study of Mus musculus with 12 samples.

How the data were processed

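Gene expression was measured by RNA sequencing of liver from 12 mouse samples. Per the labels' protocols, total RNA was extracted with TRIzol, mRNA was selected on oligo(dT) beads with a NEBNext kit, and libraries were made with a ThruPLEX kit. The authors deposited 1 table of the whole series with a column of values per library, and its file name gives the unit as RPKM, reads scaled by the length of the gene and by the mapped reads of the library. Alignment with Bowtie 1.0.0, Cuffdiff 2.1.1 and the genome build mm9 are named in the submitters' processing notes, without their roles. The gene annotation, the filters and the handling of duplicate reads are not given in the sources used here. Strand is not stated either, so reads of overlapping and antisense genes cannot be told apart. No genome coordinates are given, because the reference at hand was of another build, and it served only for transcript length and GC content (23540 genes matched by symbol).

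The table held 23936 named lines. Of these, 27 carried a spreadsheet date number in place of a gene symbol (0.16% to 0.20% of the RPKM of a library) and were left out of the comparisons, which leaves 23909 genes, 7236 of them listed at 0 in every library. Value columns with no sample numbered 0. Columns were assigned to samples by the library code in the sample titles. Rank correlations between libraries were 0.951 to 0.968 (Spearman), and no pair held identical values. Relative depth was read from the steps between low values (below 0.6 RPKM, with ratios of whole reads matched within 0.1%), since 1 read has the same worth in every library apart from depth. JAX 1 was set to 1, and the number of reads was estimated from the step and the transcript length. On simulated values of 8000 genes this gave relative depths with an error of 0.000%. The estimates were 1530000 to 3800000 reads, a ratio of 2.48, and 1 read in a transcript of 2000 nucleotides was worth 0.33 to 0.13 RPKM. These are estimates, and absolute numbers depend on the transcript lengths of an annotation that the authors need not have used.

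From the deposited RPKM, log2(RPKM + 0.5) was computed with no further scaling, so that fold changes of low genes are understated. Genes entered with at least 1 RPKM in at least 3 libraries (12058 genes). One limma-trend model (limma 3.58.1 in R 4.3.3) was fitted to the 4 groups of 3 libraries with no block, and 6 contrasts were tested, two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. The contrasts were TAC against JAX, CoJAX against JAX, CoTAC against TAC, CoTAC against CoJAX, the average of the vendor differences apart and cohoused, and the difference between these (the interaction). With 3 libraries against 3 an exact permutation test of a gene cannot go below 0.1, so the spread was shared across genes and groups. On data simulated from these libraries for TAC against JAX (12058 genes, 200 of them changed), the fit recovered 65% of genes changed by a log2 of 1 and 92% of those changed by a log2 of 2, all with the right sign, and 7 of its 164 calls were false. In a simulated comparison without changes it made 0 calls. The simulated noise was normal and independent between genes and libraries. It held no effects shared across genes, such as those of depth, so the simulation does not show how many calls such effects would make.

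Before the data were examined, 38 lists of liver pathway, cell type and stress genes were fixed, and 36 were tested with camera at a preset correlation of 0.01 between genes, with adjustment over the lists of a contrast. Camera with an estimated correlation and fry were the alternatives. Of the list calls made in the 6 contrasts, 1 held with an estimated correlation, that of NRF2 targets and glutathione genes between CoTAC and CoJAX. This one was lost when median-ratio or quantile scaling was combined with it. Of the alternatives described below, the clock score kept 1 call at the estimated correlation and the correction of high values kept 2, all between CoTAC and CoJAX. Members are counted past the threshold over all genes and when adjusted over the list alone. The genes named follow a rule also fixed before the data were examined. For each contrast it takes the 10 higher and 10 lower genes with the largest change among those that passed and whose groups did not overlap (for the vendor average and the interaction, those that passed), without unnamed gene models. Where fewer than 5 passed it takes the 5 with the smallest p. It adds up to 4 members of a list that passed over all genes or over the list alone, or the 2 with the smallest p, and always Nnt, Cyp2e1, Cyp1a2, Cyp3a11, Cyp2b10, Cyp7a1, Cyp8b1, Xist and Ddx3y. Results of a few further genes that the rule admits are not reported here. The text names a part of the genes that the rule admits. Members of the Mup, Serpina1, Saa, Cyp2c, Cyp3a, Cyp4a, Ugt1a, H2, Hba and Hbb families share reads with near-identical copies and are uncertain. Where a group was listed at 0, values per library are given and no fold.

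The alternatives fixed beforehand were pseudocounts of 0.1 and 1, other filters on low values, median-ratio and quantile scaling, the fit without the trend, robust and weighted fits, fits of the compared groups alone, a replicate block, and leaving out each library. After the data were seen, depth and a clock score (the first principal component of 20 circadian genes) were added as covariates, together with an adjustment for transcript length, GC content and level, a correction of values near the upper level, and fits without abundant genes, without small RNA genes and without TAC 1, CoJAX 1 and CoJAX 2. Other splits of the libraries were counted, 10 for each pair of groups and 100 drawn for the remaining results. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 read the table, made the depth estimates and drew the figures.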

Results

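Liver RNA was sequenced from C57BL/6 mice of 2 vendors, Jackson (JAX) and Taconic (TAC), after 4 weeks of shared housing. Mice kept with others from their own vendor formed the JAX and TAC groups. Jackson mice caged with Taconic mice formed the CoJAX group, and their Taconic cage mates formed the CoTAC group. Each of the 4 groups held 3 libraries, 12 in all. The series asks how different gut microbes affect gene expression in the liver. Cage mates exchange gut microbes by eating each other's droppings, while each mouse keeps the genome of its own colony. The labels list the libraries as separate samples without saying that each came from a separate animal, so p-values measure the spread between these samples, which may be technical. Cages are not given either, and cage mates share microbes, so cage could not enter the fits. The deposited table holds RPKM (reads mapped to a gene, scaled by its length and by the reads mapped in the library). From the steps between its lowest values the JAX libraries held an estimated 1530000 to 2020000 reads and the TAC libraries 1610000 to 3540000. The CoJAX libraries held 2200000 to 3800000 reads and the CoTAC libraries 3210000 to 3720000. A single read in a transcript of 2000 nucleotides was worth 0.33 RPKM at the lowest depth and 0.13 RPKM at the highest, and this is the resolution behind the low values. Group values below are mean RPKM ± SD (n = 3), and differences are log2(RPKM + 0.5) ± SE with adjusted p-values from limma-trend.

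Many of the most abundant liver transcripts lay near a common level in each library. Alb, which encodes serum albumin, was listed at 511.5 RPKM in CoJAX 3 and at 1151.6 RPKM in JAX 3, and its coefficient of variation over the 12 libraries was 30.9%, against 3.92% once each value was multiplied by relative depth. Hp, Ftl1 and Apoa1, which encode haptoglobin, ferritin light chain and the main protein of high-density lipoprotein, lay at 87.8% to 97.0%, 96.7% to 106.5% and 97.6% to 106.9% of the Alb value of the same library. Of 12058 genes tested, 73 had a mean above 80% of Alb, 284 above 50% and 791 above 25%. The Alb level was not a limit for every gene: 48 lay above 110% of Alb in at least 1 library, and the 14 above 200% were all small RNA genes such as Mir703. All 3 JAX libraries and TAC 1 stood apart from the other 8 libraries. They were also the shallowest, at relative depths of 0.7581 to 1 against 1.0541 to 1.8788. Their Alb level corresponded to 1.757 to 1.848 reads per base against 1.930 to 1.956 elsewhere, and the gene model Mir703 was listed at 6106 to 10054 RPKM in them against 2179 to 3951 RPKM elsewhere. On the first principal component (32.4% of the variance) the JAX libraries lay at -40.2, -48.5 and -49.8 and TAC 1 at -25.3, while the remaining libraries lay between 3.4 and 44.5. Its correlation with log depth over the 12 libraries was 0.84. CoJAX 1 and CoJAX 2 stood apart in their small nucleolar and other small RNA genes, with a median of 360 and 412 RPKM against 0 to 24.8 in the others. Values also changed with transcript length. The slope of the log2 deviation from the mean library per doubling of length was -0.148 to -0.132 in JAX, -0.084 to 0.074 in TAC, -0.089 to 0.063 in CoJAX and 0.133 to 0.167 in CoTAC.

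**Figure D1:**
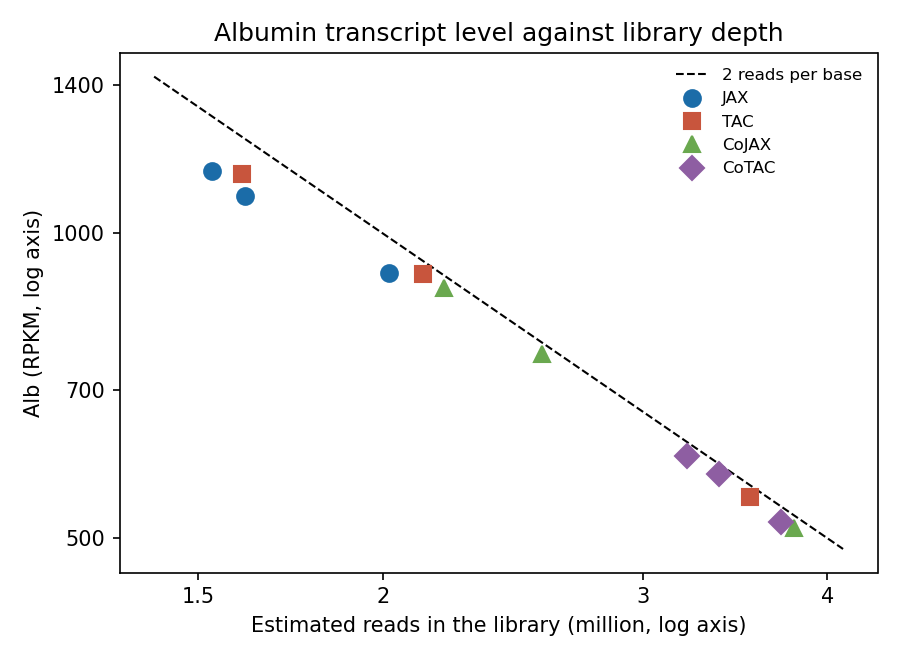
Alb RPKM of each of the 12 libraries (vertical log axis) against the estimated number of reads in the library (horizontal log axis), marked by group. Alb lay at 1151.6 RPKM in the shallowest library, JAX 3, and at 511.5 RPKM in the deepest, CoJAX 3.

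TAC livers were compared with JAX livers to measure how the colonies differed when kept apart. Several transcripts of fatty acid metabolism were lower in TAC. Cyp4a10 and Cyp4a14, which encode omega-hydroxylases of fatty acids, averaged 19.1 ± 9.64 and 5.86 ± 1.54 RPKM in TAC against 136 ± 19.2 and 142 ± 47.6 RPKM in JAX. Their log2 differences were -2.91 ± 0.31 (adjusted p = 0.00468) and -4.46 ± 0.63 (adjusted p = 0.0115). Cyp4a31 fell by 1.60 ± 0.30 (adjusted p = 0.0267), and because Cyp4a genes are near-identical, reads of one member can be counted for another. The acyl-CoA thioesterases Acot2 and Acot3 fell by 2.17 ± 0.36 and 2.15 ± 0.39 (adjusted p = 0.0197 and 0.0263), and the peroxisomal fatty acid transporter Abcd2 fell by 2.34 ± 0.46 (adjusted p = 0.0281). Of 24 measured PPARα targets 5 were lower, 0 were higher and 19 did not pass (7 lower when adjusted over the list alone). The camera test called the list lower (adjusted p = 0.00599), and the call was lost at adjusted p = 0.848 with an estimated correlation.

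Among genes higher in TAC, Moxd1, which encodes a monooxygenase-like protein, averaged 113 ± 58.2 RPKM against 0.208 ± 0.212 RPKM in JAX (log2 difference 7.21 ± 0.99, adjusted p = 0.0105). Asparagine synthetase, Asns, averaged 27.2 ± 6.62 against 4.23 ± 1.87 RPKM (2.59 ± 0.44, adjusted p = 0.022). The calpain gene Capn8, the zinc finger gene Zfp791 and the ferritin receptor gene Scara5 rose by 2.37 ± 0.29, 3.23 ± 0.41 and 2.03 ± 0.33 (adjusted p = 0.00994, 0.00994 and 0.0197). Of 14 genes of the unfolded protein response 3 were higher and 0 lower (6 higher when adjusted over the list alone), among them the chaperone Hyou1 (1.11 ± 0.28, adjusted p = 0.0493) and the transcription factor Xbp1 (0.47 ± 0.12, adjusted p = 0.0458). The camera adjusted p of this list was 0.0286, and adjusted p = 0.848 with an estimated correlation. The heat shock genes Hsph1 and Hspa1b rose by 1.38 ± 0.22 and 1.42 ± 0.32 (adjusted p = 0.0197 and 0.0376), 2 of 12 measured members, and that list was not called (camera adjusted p = 0.22). The urea cycle gene Cps1 (0.69 ± 0.16, adjusted p = 0.0367) and the glucuronosyltransferase Ugt1a6a (0.91 ± 0.19, adjusted p = 0.0323) were also higher, Ugt1a6a with reads that near-identical Ugt1a genes can share.

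Lower in TAC were also glutathione transferases and a lipid transfer gene. Gsta2 averaged 33.9 ± 3.73 RPKM in TAC and 103 ± 20.7 RPKM in JAX (-1.57 ± 0.29, adjusted p = 0.0263), and Gsta4 and the malic enzyme Me1 fell by 0.64 ± 0.15 and 0.70 ± 0.15 (adjusted p = 0.0409 and 0.0352). Of 19 measured NRF2 targets and glutathione genes 3 were lower and 0 higher (4 lower and 1 higher when adjusted over the list alone; camera adjusted p = 0.037, and adjusted p = 0.842 with an estimated correlation). All 16 measured CAR targets had negative differences and 0 passed over all genes or when adjusted over the list alone (camera adjusted p = 0.0229, and adjusted p = 0.842 with an estimated correlation). Of these targets 7 lay above 25% of the Alb level, and the 791 genes above that level had a median difference of -0.28. The phospholipid transfer protein Pltp averaged 41.6 ± 12.8 against 166 ± 18.5 RPKM (-2.02 ± 0.35, adjusted p = 0.0243), and Cib3 fell by 2.78 ± 0.62 (adjusted p = 0.0367). Among markers of other cell types, the B cell gene Cd79a fell by 1.79 ± 0.34 (adjusted p = 0.0269), the 1 of 10 leukocyte markers that passed (also 1 over the list alone; camera adjusted p = 0.515). Of 12 stellate cell and fibroblast markers 0 passed over all genes and 4 were lower when adjusted over the list alone (camera adjusted p = 0.0286, and adjusted p = 0.848 with an estimated correlation). Ribosomal protein and oxidative phosphorylation lists were called lower as well (camera adjusted p = 0.00599 and 0.0418, both at adjusted p = 0.848 with an estimated correlation), with 16 of 18 and 18 of 20 members above 25% of the Alb level. In all, 493 genes passed, 287 higher and 206 lower (3163 at an unadjusted p under 0.05, with 603 expected by chance), and 26.2% of genes had groups that did not overlap, against 10% by chance. Of the 7 list calls only those for the unfolded protein response and for stellate markers were made again under quantile normalization, with adjusted p = 0.00707 and 0.0176. The 7 calls were 1 higher and 6 lower, while quantile normalization called 9 higher and 3 lower. The count was 132 with depth as a covariate, and without one library it was 42 (JAX 1), 79 (JAX 2), 27 (JAX 3), 2113 (TAC 1), 11 (TAC 2), 41 (TAC 3), 264 (CoJAX 1), 248 (CoJAX 3), 298 (CoTAC 1) or 254 (CoTAC 3). All 27 genes named for this comparison kept their sign without any library, and 5 of them stayed past the threshold without TAC 2, the fewest. The fit with depth kept 16 of them past it, and there the median difference of the 493 genes was 0.68 (median SE 0.18) against 0.75 (0.16).

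Of 5 measured genes known to differ between C57BL/6 substrains, 4 passed between TAC and JAX and 3 between CoTAC and CoJAX. Nnt, the mitochondrial transhydrogenase gene that is partly deleted in the C57BL/6J substrain, averaged 18.7 ± 1.56 RPKM in JAX and 29.4 ± 4.24 RPKM in CoJAX, against 54.7 ± 8.52 RPKM in TAC and 60.8 ± 6.03 RPKM in CoTAC. The labels give the strain of all mice as C57BL/6 without a substrain. The TAC and JAX difference in Nnt was 1.51 ± 0.14 (adjusted p = 0.00228), and every Taconic library lay above every Jackson library. Wdfy1 averaged 16.5 ± 3.31 and 21.5 ± 1.21 RPKM in TAC and CoTAC against 7.96 ± 1.68 and 4.23 ± 0.615 RPKM in JAX and CoJAX, and was higher in TAC than in JAX by 1.005 ± 0.18 (adjusted p = 0.0256). Ide, which encodes the insulin-degrading enzyme, averaged 36.7 ± 0.870 and 37.0 ± 2.39 RPKM in TAC and CoTAC against 55.4 ± 4.28 and 63.9 ± 4.96 RPKM in JAX and CoJAX (TAC against JAX -0.58 ± 0.10, adjusted p = 0.0201). Fgfbp3 averaged 0.457 ± 0.255 RPKM in TAC and 2.47 ± 1.02 RPKM in JAX (-1.61 ± 0.36, adjusted p = 0.0368), near the value of a few reads, and the cohoused groups overlapped (0.939 to 2.061 RPKM in CoJAX and 0.356 to 1.124 RPKM in CoTAC). Crb1, the retinal gene mutated in the C57BL/6N substrain, was listed at 0 in all 12 libraries.

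**Figure D2:**
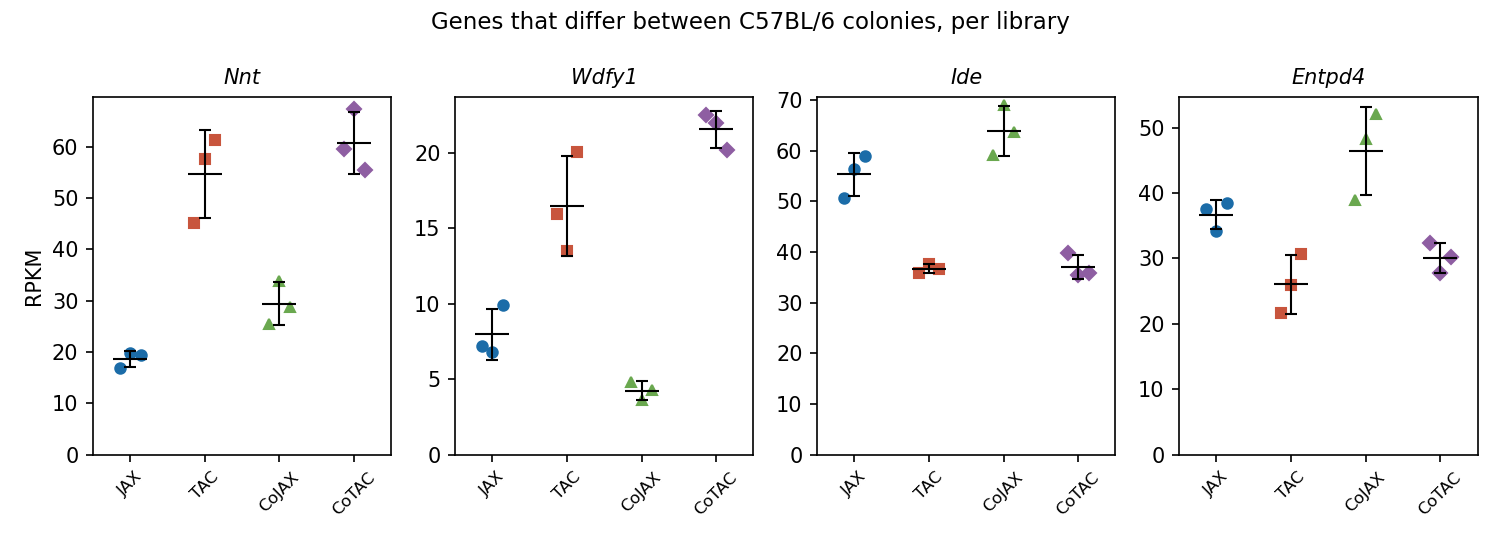
RPKM of Nnt, Wdfy1, Ide and Entpd4 in each library (points) with the group mean and SD (n = 3) for JAX, TAC, CoJAX and CoTAC. Nnt averaged 54.7 and 60.8 RPKM in the groups of Taconic mice and 18.7 and 29.4 RPKM in the groups of Jackson mice, and Ide was lower in the Taconic groups (36.7 and 37.0 RPKM against 55.4 and 63.9).

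CoJAX livers were compared with JAX livers to ask what differed in Jackson mice that lived with Taconic mice. The mitochondrial carrier Slc25a30 averaged 23.9 ± 4.29 RPKM in CoJAX and 2.51 ± 0.509 RPKM in JAX (3.02 ± 0.34, adjusted p = 0.00278). Mia2, which acts in the export of large cargo from the endoplasmic reticulum, averaged 35.1 ± 15.5 against 4.11 ± 0.475 RPKM (2.86 ± 0.53, adjusted p = 0.00644). Sntb1 and Mob1a, which encode a membrane scaffold protein and a kinase activator, rose by 2.67 ± 0.60 and 2.83 ± 0.55 (adjusted p = 0.0118 and 0.0073). Ppp1r3g, a glycogen-targeting subunit of protein phosphatase, averaged 7.83 ± 3.13 against 46.0 ± 12.4 RPKM (-2.52 ± 0.56, adjusted p = 0.0114). Cabyr and Nrgn, both encoding calcium or calmodulin binding proteins, fell by 2.23 ± 0.49 and 2.57 ± 0.36 (adjusted p = 0.0105 and 0.00439). Prok1 was listed at 0 in JAX and at 6.17, 7.06 and 4.77 RPKM in the CoJAX libraries (adjusted p = 0.00593). The small nucleolar RNA gene Snord89 was listed at 0 in JAX and at 973, 1669 and 564 RPKM in CoJAX (adjusted p = 0.00616). Snora81 was also listed at 0 in JAX, and at 730, 659 and 22.3 RPKM in CoJAX (adjusted p = 0.00527). CoJAX 1 and CoJAX 2, where these values were highest, are the libraries whose small RNA genes stood apart.

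Conjugation and bile transport genes were among those higher in CoJAX. Of 18 measured UGT and SULT genes 6 were higher and 0 lower (6 higher when adjusted over the list alone), with Ugt1a1 and Ugt1a9 up by 0.67 ± 0.15 and 1.26 ± 0.25 (adjusted p = 0.0116 and 0.00775), members of a near-identical family. Of 9 genes of FXR regulation 4 were higher and 0 lower (also 4 higher when adjusted over the list alone). They were the nuclear receptors Nr5a2 (1.32 ± 0.24, adjusted p = 0.00616) and Hnf4a (0.57 ± 0.14, adjusted p = 0.0147), the bile salt export pump Abcb11 (0.38 ± 0.10, adjusted p = 0.0234) and the phospholipid exporter Abcb4 (0.35 ± 0.12, adjusted p = 0.0473). The conjugate exporter Abcc2 rose by 0.93 ± 0.22 (adjusted p = 0.0138), and Acsm3, a medium-chain acyl-CoA synthetase, by 1.35 ± 0.25 (adjusted p = 0.00644). The camera adjusted p was 0.236 for UGT and SULT genes and for FXR regulation, so neither list was called against the other genes. Of 20 lipogenesis genes 4 were higher, 1 was lower and 15 did not pass (4 and 1 also when adjusted over the list alone; camera adjusted p = 0.935), with Gpam and Fads2, of glycerolipid and polyunsaturated fatty acid synthesis, up by 1.93 ± 0.50 and 0.96 ± 0.23 (adjusted p = 0.0182 and 0.0133). Of 24 cholesterol synthesis genes 4 were higher, 1 was lower and 19 did not pass (4 and 1 also when adjusted over the list alone; camera adjusted p = 0.897). Srebf2, a regulator of cholesterol synthesis, rose by 0.89 ± 0.23 (adjusted p = 0.0198). Of 24 PPARα targets 3 were higher and 0 lower (2 higher when adjusted over the list alone; camera adjusted p = 0.993), including Cpt1a and Hadha, of mitochondrial fatty acid oxidation (0.76 ± 0.20 and 0.47 ± 0.11, adjusted p = 0.0212 and 0.0125). The CAR target Cyp2b10 averaged 10.96 ± 3.66 RPKM in CoJAX and 3.46 ± 0.294 RPKM in JAX (1.49 ± 0.40, adjusted p = 0.0206), 1 of 16 CAR targets that were higher, with 1 lower (camera adjusted p = 0.5). With depth as a covariate none of these conjugation, transport and lipid genes passed. In that fit Gpam, Fads2 and Cyp2b10 were at 0.97 ± 0.49, 0.71 ± 0.27 and 0.98 ± 0.47. Nr5a2, Acsm3 and Srebf2 were also smaller, at 0.87 ± 0.24, 0.86 ± 0.24 and 0.57 ± 0.28. Hnf4a, Abcb11, Abcb4 and Hadha, at 0.58 ± 0.17, 0.46 ± 0.11, 0.38 ± 0.14 and 0.48 ± 0.12, kept their differences at a larger SE. Of the substrain genes, Nnt was higher in CoJAX by 0.63 ± 0.14 (adjusted p = 0.0118) and Wdfy1 lower, at -0.83 ± 0.18 (adjusted p = 0.0104).

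Some genes of the interferon response and of innate sensing were lower in CoJAX, in lists that were not called. Of 25 interferon response genes 4 were lower and 0 higher (3 lower when adjusted over the list alone; camera adjusted p = 0.285), namely the immunoproteasome subunit Psmb8 (-0.58 ± 0.12, adjusted p = 0.00802), Irf7 (-0.48 ± 0.11, adjusted p = 0.0123), Xaf1 (-0.87 ± 0.20, adjusted p = 0.013) and Isg15 (-0.72 ± 0.23, adjusted p = 0.0433). Of 15 microbial sensing and cytokine genes the NF-κB inhibitor Nfkbia (-0.72 ± 0.13, adjusted p = 0.00616) and the TLR4 co-receptor Ly96 (-1.01 ± 0.24, adjusted p = 0.0141) were lower and 0 were higher (also 2 lower when adjusted over the list alone; camera adjusted p = 0.704). Unfolded protein response genes went both ways, with Hyou1 and Xbp1 up by 1.28 ± 0.28 and 0.51 ± 0.12 (adjusted p = 0.0108 and 0.0118) and Atf4 down, at -0.71 ± 0.15 (adjusted p = 0.00865). Of 18 ribosomal protein genes 6 were lower and 0 higher (13 lower when adjusted over the list alone), such as Rpl27 and Rps18 (-0.76 ± 0.20 and -0.77 ± 0.24, adjusted p = 0.0216 and 0.0366). These were -0.27 and -0.20 with depth as a covariate and -0.42 and -0.15 under quantile normalization. This was the one list called (camera adjusted p = 0.000259), the call was lost at adjusted p = 0.976 with an estimated correlation and under quantile normalization (adjusted p = 0.0635), and 16 of its members lay above 25% of the Alb level. Of 20 oxidative phosphorylation genes 2 were higher and 7 lower (2 and 11 when adjusted over the list alone; camera adjusted p = 0.0905), for example Ndufs1 at 0.71 ± 0.13 (adjusted p = 0.00675) and Cox7b at -0.80 ± 0.22 (adjusted p = 0.0245), which was -0.24 with depth as a covariate. In all, 2911 genes passed, 24.1% of those tested, 1529 higher and 1382 lower (4676 at an unadjusted p under 0.05), and groups did not overlap in 43.7% of genes against 10% by chance. Among the 791 genes above 25% of the Alb level 26 were higher and 264 lower, and among the others 1503 and 1118. With depth as a covariate 39 genes passed and all 2911 kept their sign. Of the 39 genes named here as passing, 3 passed in that fit (Slc25a30, Nrgn and Xbp1), and 12 differences changed by more than 1.5 times. Under quantile normalization 38 passed, and 25 without CoJAX 2, the fewest for any library. The count was 1672 without JAX 2, 1435 without JAX 3, 1264 without CoJAX 2, 1605 without CoJAX 3 and 1121 without TAC 1, CoJAX 1 and CoJAX 2 together.

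CoTAC livers were compared with TAC livers to ask what differed in Taconic mice that lived with Jackson mice. Slc25a30 was again higher, at 63.1 ± 25.1 RPKM in CoTAC and 6.52 ± 3.62 RPKM in TAC (3.24 ± 0.34, adjusted p = 0.00781). Some Cyp4a genes were higher: Cyp4a10 averaged 69.5 ± 1.83 against 19.1 ± 9.64 RPKM (1.96 ± 0.31, adjusted p = 0.0222), and Cyp4a31 and Cyp4a32 rose by 2.29 ± 0.30 and 0.97 ± 0.19 (adjusted p = 0.00853 and 0.0397), with reads that near-identical members can share. Cyp4a14 did not pass in this comparison. Of 24 PPARα targets 3 were higher and 0 lower (7 higher and 1 lower when adjusted over the list alone), and the list was not called (camera adjusted p = 0.0696). Scara5 averaged 57.9 ± 14.8 against 13.8 ± 3.73 RPKM (2.03 ± 0.33, adjusted p = 0.0227). The cytokine signalling inhibitor Socs3 and the activin subunit gene Inhbe each rose by 1.83 (SE 0.34 and 0.36, adjusted p = 0.0378 and 0.0455). The small GTPase Rab30 rose by 1.70 ± 0.20 (adjusted p = 0.00781) and the translation factor Ctif by 1.56 ± 0.20 (adjusted p = 0.00853).

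Heat shock genes were among those lower in CoTAC than in TAC. Hspa1b, an inducible HSP70 gene, averaged 6.24 ± 0.722 against 37.6 ± 12.1 RPKM (-2.45 ± 0.32, adjusted p = 0.00853), its near-identical neighbour Hspa1a differed by -2.37 ± 0.34 (adjusted p = 0.0161) and the co-chaperone Dnajb1 by -1.02 ± 0.19 (adjusted p = 0.0352). Of 12 heat shock genes these 3 were lower and 0 higher (4 lower when adjusted over the list alone; camera adjusted p = 1.82e-05, and adjusted p = 0.199 with an estimated correlation). Ddit4, an mTORC1 inhibitor, and Tsc22d3, both induced by glucocorticoids, averaged 31.0 ± 16.5 and 94.0 ± 27.1 RPKM in CoTAC against 147 ± 55.1 and 255 ± 31.5 RPKM in TAC (-2.30 ± 0.35 and -1.47 ± 0.19, adjusted p = 0.0197 and 0.00853). Arrdc2, the chemokine receptor Cxcr4 and the collagen prolyl hydroxylase P4ha1 fell by 1.82 ± 0.23, 1.68 ± 0.30 and 1.52 ± 0.23 (adjusted p = 0.00853, 0.0301 and 0.0197). Insig1, a brake on sterol synthesis, and the periportal gene Etnppl fell by 0.76 ± 0.12 and 1.13 ± 0.21 (adjusted p = 0.0222 and 0.0372). Of 19 NRF2 targets and glutathione genes only Gsta4 passed over all genes (-0.87 ± 0.15, adjusted p = 0.0271), and 8 were lower when adjusted over the list alone, among them Gstm2 (-0.75 ± 0.16, adjusted p = 0.0527 over all genes). The camera adjusted p of that list was 4.44e-05, and adjusted p = 0.141 with an estimated correlation. Of 13 endothelial markers 0 passed over all genes and 10 were lower when adjusted over the list alone (camera adjusted p = 1.54e-05, and adjusted p = 0.622 with an estimated correlation). Pecam1 and Clec4g differed by -1.13 ± 0.29 and -1.04 ± 0.29 (adjusted p = 0.0853 and 0.0939). Pecam1 was listed at 3.12, 6.07 and 2.099 RPKM in CoTAC 1, 2 and 3.

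The endothelial median of CoTAC, relative to the mean of all libraries, was -1 in CoTAC 1, 0.02 in CoTAC 2 and -1.39 in CoTAC 3, and that of NRF2 targets and glutathione genes was -0.42, -0.29 and -0.41. In all, 13 lists were called lower, 0 of them with an estimated correlation (adjusted p = 0.141 to 0.622 with an estimated correlation), and 5 of the 13 were called again under quantile normalization. Adjustment for transcript length and GC content, with which the CoTAC libraries trend, kept 4 of the 13. Between CoTAC and TAC 78 genes passed, 45 higher and 33 lower (2964 at an unadjusted p under 0.05), with groups apart in 26.4% of genes against 10% by chance. With depth as a covariate 6 genes passed, 5 of them among the 20 named, while the median difference of the 78 was 1.03 (median SE 0.20) against 1.06 (0.18). Without one library the count was 9 (TAC 1), 14 (TAC 2), 1530 (TAC 3), 21 (CoTAC 1), 376 (CoTAC 2) or 2 (CoTAC 3), and of 20 genes named here as passing, all of which kept their sign, 1 stayed past the threshold without CoTAC 3. Nnt did not pass in this comparison (0.16 ± 0.14, adjusted p = 0.504).

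**Figure D3:**
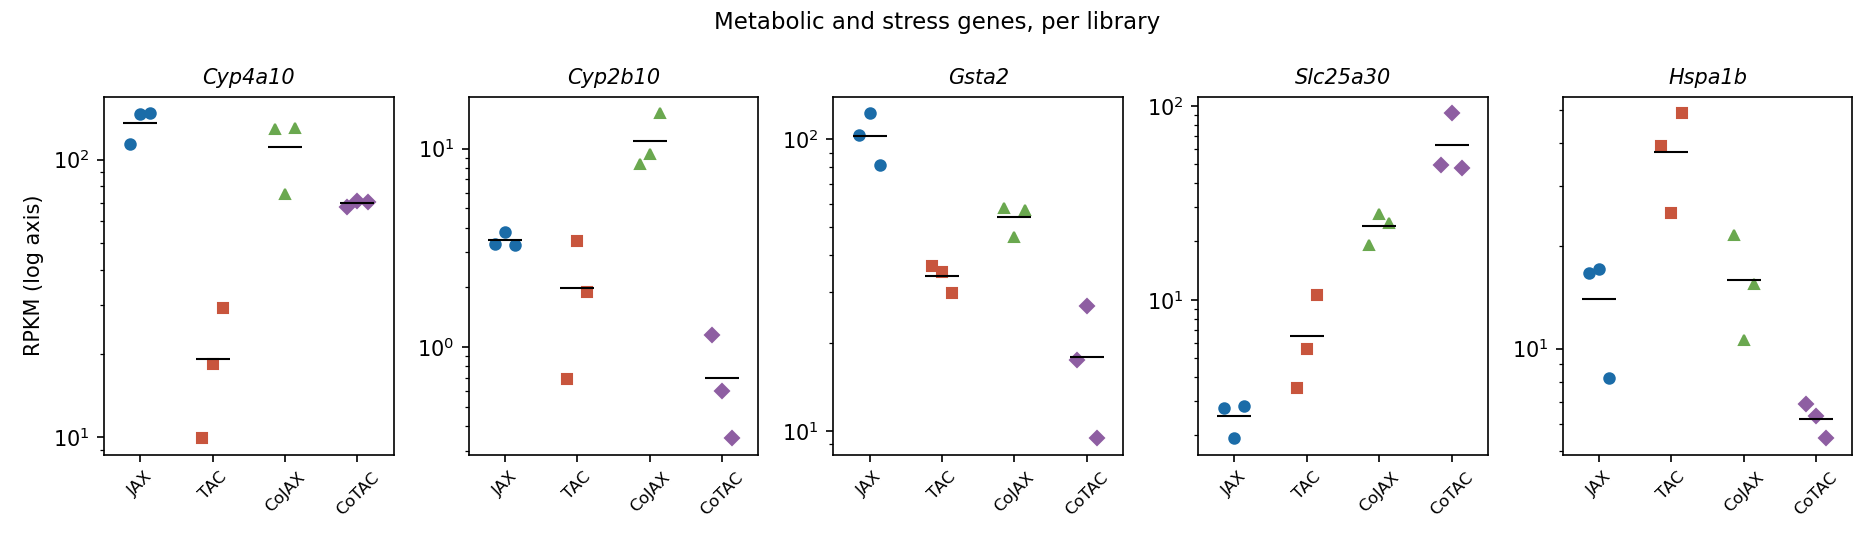
RPKM on a log axis of Cyp4a10, Cyp2b10, Gsta2, Slc25a30 and Hspa1b in each library (points), with lines at the group means (n = 3) of JAX, TAC, CoJAX and CoTAC. Cyp4a10 averaged 136, 19.1, 111 and 69.5 RPKM in that order, and Slc25a30 averaged 2.51, 6.52, 23.9 and 63.1 RPKM.

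CoTAC livers were compared with CoJAX livers to measure how the vendors differed after they had lived together. Wdfy1 was higher in CoTAC by 2.23 ± 0.18 (adjusted p = 0.000439), Nnt by 1.04 ± 0.14 (adjusted p = 0.0193) and Mid1, an X-linked ubiquitin ligase gene, by 1.86 ± 0.24 (adjusted p = 0.0131). Ide was lower at -0.78 ± 0.10 (adjusted p = 0.0112). Cyp2b10, the classic target of the receptor CAR, averaged 0.701 ± 0.414 RPKM in CoTAC and 10.96 ± 3.66 RPKM in CoJAX (-3.26 ± 0.40, adjusted p = 0.0112). Cyp26a1, which breaks down retinoic acid, averaged 10.8 ± 2.79 against 124 ± 77.7 RPKM (-3.23 ± 0.47, adjusted p = 0.0316). The histone gene Hist1h4f was listed at 2.82, 2.42 and 1.63 RPKM in CoJAX and at 0 in the other 9 libraries (adjusted p = 0.0098). Values this low rest on few reads, and the gene met the filter only through the CoJAX libraries. These 7 and a gene model without a name of its own made up the 8 genes that passed, 3 higher and 5 lower (1304 at an unadjusted p under 0.05), with groups apart in 19% of genes against 10% by chance.

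Gene lists were also tested between CoTAC and CoJAX. Of 16 CAR targets 1 was lower and 0 higher over all genes and 9 were lower when adjusted over the list alone, including Cyp2c54, Cyp2c37 and Gstm3 (-0.84 ± 0.17, -0.69 ± 0.16 and -0.70 ± 0.17, adjusted p = 0.14, 0.181 and 0.201 over all genes), of which the Cyp2c genes have near-identical relatives. The camera adjusted p of CAR targets was 5.9e-09, and adjusted p = 0.0516 with an estimated correlation. Of these targets 7 lay above 25% of the Alb level, and the 791 genes above that level had a median difference of -0.25. Of 19 NRF2 targets and glutathione genes 0 passed over all genes and 8 were lower when adjusted over the list alone, including Gsta2 and Gsta4 (-1.68 ± 0.29 and -0.92 ± 0.15, adjusted p = 0.0713 and 0.0559). Their camera adjusted p was 4.97e-07, and with adjusted p = 0.0453 with an estimated correlation this was the only one of all 61 list calls that held under that setting. It was lost again when median-ratio scaling was combined with that setting (adjusted p = 0.0577), as it was with quantile normalization (0.326), depth (0.0611) or length and GC (0.265). At the estimated correlation the replicate block kept 0 of the 19 list calls of this comparison, the clock score 1 and the correction near the upper level 2. Of 13 endothelial markers 0 passed over all genes and 12 were lower when adjusted over the list alone, among them Clec4g and Oit3 (-1.16 ± 0.29 and -1.43 ± 0.35, adjusted p = 0.221 and 0.21; camera adjusted p = 2.43e-09, and adjusted p = 0.254 with an estimated correlation). In CoTAC 1, 2 and 3 Clec4g was listed at 31.4, 68.3 and 27.4 RPKM. In all, 18 lists were called lower and 1 higher, the acute phase genes (25 measured, 0 past the threshold; camera adjusted p = 0.0216, and adjusted p = 0.665 with an estimated correlation). Quantile normalization kept 8 of the 19 calls and turned the direction of PPARα targets, bile acid synthesis and ribosomal proteins, 7 of 24, 9 of 14 and 16 of 18 of whose members lay above 25% of the Alb level. Adjustment for length and GC content kept 10 of the 19 and turned ribosomal proteins. Over all 6 comparisons the 61 calls were 14 higher and 47 lower, against 36 and 22 under quantile normalization and 25 and 26 after the length and GC adjustment. With depth as a covariate 5 genes passed, and the count was 3 without CoJAX 1, 229 without CoTAC 2 and 2 without CoTAC 3. The 7 named genes kept their sign throughout, 4 of them passed with depth and 2 without CoTAC 3.

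The vendor average is the mean of the differences between vendors apart and cohoused, and one housing can carry it. Nnt (1.28 ± 0.10) and Wdfy1 (1.62 ± 0.13) were higher in Taconic mice, both at adjusted p = 0.000164, and Ide (-0.68 ± 0.07, adjusted p = 0.00159) and Entpd4 (-0.55 ± 0.10, adjusted p = 0.0258) were lower. Moxd1 rose by 6.20 ± 0.70 (adjusted p = 0.00255), with 1.33, 29.8 and 0.342 RPKM in the CoJAX libraries and 136 ± 37.2 RPKM in CoTAC. Asns, Scara5 and Camk2b, a calmodulin kinase gene, rose by 2.42 ± 0.31, 1.81 ± 0.24 and 1.81 ± 0.24 (all at adjusted p = 0.00483). Capn8, Zfp791 and the phospholipase gene Plcd3 rose by 2.01 ± 0.21, 2.44 ± 0.29 and 2.20 ± 0.29 (adjusted p = 0.00159, 0.00358 and 0.00539). Cyp2b10 was lower at -2.04 ± 0.28 (adjusted p = 0.00601), with Cyp2c54, Cyp2c37 and Gstm3 at -0.63 ± 0.12, -0.46 ± 0.11 and -0.48 ± 0.12 (adjusted p = 0.0263, 0.0458 and 0.0466). These were the 4 of 16 CAR targets that passed, all lower (10 lower when adjusted over the list alone; camera adjusted p = 2.91e-06, and adjusted p = 0.124 with an estimated correlation). Of the 16, 7 lay above 25% of the Alb level, and the 791 genes above that level had a median vendor average of -0.27. Of 19 NRF2 targets and glutathione genes 6 were lower and 0 higher (10 lower and 1 higher when adjusted over the list alone). Among them were Gsta2 (-1.62 ± 0.20, adjusted p = 0.00414), Gsta4 (-0.78 ± 0.11, adjusted p = 0.00601), Me1 (-0.58 ± 0.11, adjusted p = 0.0263) and the quinone reductase Nqo1 (-0.65 ± 0.13, adjusted p = 0.0304). The camera adjusted p of this list was 7.58e-05, and adjusted p = 0.124 with an estimated correlation.

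Of 24 PPARα targets 4 were lower in the vendor average and 0 higher (8 lower when adjusted over the list alone): Cyp4a10 (-1.77 ± 0.22, adjusted p = 0.00414), Cyp4a14 (-2.67 ± 0.45, adjusted p = 0.0165), the pantetheinase Vnn1 (-1.12 ± 0.23, adjusted p = 0.0314) and Acot2 (-1.21 ± 0.25, adjusted p = 0.0342). Their camera adjusted p was 0.000165, and adjusted p = 0.586 with an estimated correlation. Targets passed in mice kept apart, while between CoTAC and CoJAX 0 targets passed over all genes or the list alone (camera adjusted p = 0.0097, and adjusted p = 0.382 with an estimated correlation). There Cyp4a10, Cyp4a14, Vnn1 and Acot2 differed by -0.63 ± 0.31, -0.89 ± 0.63, -0.55 ± 0.32 and -0.26 ± 0.36 (adjusted p = 0.487 to 0.783). The interaction test did not call PPARα targets, so a difference between the housings was not shown for the list. Upp1, a uridine phosphorylase gene, Serpinb1a, an inhibitor of neutrophil proteases, and Abcd2 fell by 1.77 ± 0.23, 1.79 ± 0.32 and 1.79 ± 0.33 (adjusted p = 0.00483, 0.0233 and 0.026). Among markers of other cell types, the bile duct tight junction gene Cldn7 (-1.58 ± 0.23, adjusted p = 0.00934) and Cd79a (-1.499 ± 0.24, adjusted p = 0.0133) were lower, each the 1 of 10 cholangiocyte or leukocyte markers that passed (camera adjusted p = 0.101 and 0.45). So were the endothelial genes Stab1 and Eng (-0.67 ± 0.15 and -0.63 ± 0.15, adjusted p = 0.0426 and 0.0474) and the stellate cell gene Ecm1 (-0.88 ± 0.17, adjusted p = 0.0284). Of 13 endothelial and 12 stellate cell markers 2 and 1 were lower over all genes, and 10 and 7 when adjusted over the list alone (camera adjusted p = 7.82e-06 and 7.58e-05, and adjusted p = 0.628 and 0.599 with an estimated correlation). The endothelial median was -1 in CoTAC 1 and -1.39 in CoTAC 3 against 0.02 in CoTAC 2. The acute phase gene Lcn2 did not pass (2.77 ± 0.70, adjusted p = 0.0515) and was listed at 520, 19.0 and 537 RPKM in the CoTAC libraries. In all, 418 genes passed, 185 higher and 233 lower, and 596 under quantile normalization, 326 higher and 270 lower. With depth as a covariate the count was 89, and without one library it was 199 (JAX 1), 98 (JAX 2), 71 (JAX 3), 1905 (TAC 1), 74 (TAC 2), 94 (TAC 3), 44 (CoJAX 1), 73 (CoJAX 3), 53 (CoTAC 1), 812 (CoTAC 2) or 53 (CoTAC 3). All 31 passing genes named here kept their sign without any library, and 17 stayed past the threshold without CoJAX 1, the fewest. Of the 31, 21 passed with depth as a covariate, where the median difference of the 418 genes was 0.57 (median SE 0.15) against 0.61 (0.13).

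The interaction asks whether the signed difference between the vendors changed from mice kept apart to cohoused mice. A positive value means a TAC minus JAX difference above the CoTAC minus CoJAX one, and does not say which was larger in size. In this test 0 genes passed with limma-trend (1358 at an unadjusted p under 0.05, with 603 expected by chance). The 5 genes with the smallest p, none of them passing, were Rab30 (-1.94 ± 0.28, adjusted p = 0.17), Hist1h4f (adjusted p = 0.205, with the values given above) and Hspa1b (2.65 ± 0.45, adjusted p = 0.205), together with the lysosomal transporter gene Slc15a4 (1.01 ± 0.18, adjusted p = 0.205) and the GTPase gene Rraga (0.99 ± 0.17, adjusted p = 0.205). Cyp4a10 and Cyp4a31 had interaction values of -2.28 ± 0.44 and -2.25 ± 0.42 (adjusted p = 0.214 and 0.205). Those of Cyp2b10, the adhesion gene Icam1 and Wdfy1 were 2.44 ± 0.56 (adjusted p = 0.265), -1.53 ± 0.31 (adjusted p = 0.237) and -1.22 ± 0.25 (adjusted p = 0.238). Of 36 lists 12 were called higher and 1 lower, 0 of them with an estimated correlation (adjusted p = 0.377 to 0.671 with an estimated correlation), and all 13 were called again in the same direction under quantile normalization, and 8 after the length and GC adjustment. Without TAC 1 the count of genes was 46 and without CoTAC 2 it was 6.

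Across the 12058 genes, which are not independent replicates, the vendor differences apart and cohoused had a Pearson r of 0.274 and a Spearman rho of 0.321. Of the 493 genes called between TAC and JAX, 385 (78.1%) had the same sign between CoTAC and CoJAX, with a median of 0.75 in the first comparison and 0.17 in the second. Both comparisons called 2 higher and 2 lower genes, against 0.0714 and 0.0854 expected of independent lists. Cohousing changes in Jackson and in Taconic mice had r of 0.462 and rho of 0.573. Of 2911 genes called in Jackson mice 2593 (89.1%) had the same sign in Taconic mice, with a median of 0.69 and 0.33, and 74 of the 78 genes called in Taconic mice (94.9%) had the same sign in Jackson mice. Both called 28 higher and 17 lower genes, Slc25a30 among the first, against 5.71 and 3.78 expected of independent lists. The TAC and CoJAX differences from JAX use the same JAX libraries. Their r was 0.703 against 0.496 in 50 simulations of unchanged groups, and their covariance 0.238 against 0.052, a difference of 0.186. They shared 265 higher and 157 lower calls (36.4 and 23.6 expected of independent lists). Since 3 control libraries cannot be split into parts of 2 or more each, part of this excess may come from the shared controls.

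Several genes of drug and bile acid metabolism were fixed for reporting whatever their result. Cyp2e1, which oxidises ethanol and acetaminophen, averaged 856 ± 99.8, 711 ± 191, 638 ± 145 and 509 ± 21.6 RPKM in JAX, TAC, CoJAX and CoTAC, at 86.1% of the Alb level over all libraries. Its vendor average was -0.30 ± 0.16 (adjusted p = 0.242) and turned to 0.064 under quantile normalization. Cyp3a11 lay at 75.3% of the Alb level, with a vendor average of -0.31 ± 0.16 (adjusted p = 0.221) that turned to 0.03 under quantile normalization. Cyp1a2 averaged 488 ± 53.9, 429 ± 102, 361 ± 56.1 and 279 ± 28.7 RPKM in the same order of groups (vendor average -0.29 ± 0.14, adjusted p = 0.196). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, averaged 32.6 ± 6.56, 15.2 ± 5.49, 27.4 ± 31.1 and 12.4 ± 6.21 RPKM (-0.87 ± 0.43, adjusted p = 0.215). Cyp8b1, which makes cholic acid, averaged 320 ± 9.45, 290 ± 92.9, 294 ± 43.6 and 226 ± 42.3 RPKM (-0.29 ± 0.16, adjusted p = 0.258). The vendor averages of Cyp1a2 and Cyp8b1 shrank to -0.024 and -0.097 under quantile normalization. With depth as a covariate they were -0.077 and -0.071. That of Cyp7a1 was -0.91 and -0.96 in these 2 settings. Xist, expressed from the inactive X chromosome of females, was listed at 0 in 11 libraries and at 0.0208 RPKM in CoTAC 2, and the Y-linked gene Ddx3y at 15.5 to 31.1 RPKM in all 12. The labels do not give the sex of the mice.

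Genes of the circadian clock varied within each group. Dbp, a clock output gene, was listed at 77.5, 0.786 and 102 RPKM in the JAX libraries, and at 0.395, 0.595 and 94.1 RPKM in TAC. It was listed at 4.90, 144 and 19.4 RPKM in CoJAX and at 99.8, 105 and 2.96 RPKM in CoTAC. Arntl, which peaks in the opposite phase, was listed at 3.64, 14.6 and 1.77 RPKM in JAX, and at 16.9, 24.6 and 1.96 RPKM in TAC. Its values were 25.3, 1.36 and 22.9 RPKM in CoJAX and 2.76, 3.45 and 22.5 RPKM in CoTAC. The list of circadian genes was not called in any of the 6 comparisons. Camera tests for a shift of a list in one direction, and this list holds genes of opposite phase, such as Dbp and Arntl. The missing calls therefore do not show that the clock was alike between groups. With a score of these genes as a covariate, 905 genes passed between TAC and JAX in place of 493, 3377 between CoJAX and JAX in place of 2911, 11 between CoTAC and CoJAX in place of 8 and 655 in the vendor average in place of 418. Between CoTAC and TAC 68 passed, 54 of them among the 78 called without the score, and Socs3, Inhbe and Etnppl no longer passed. The interaction stayed at 0.

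**Figure D4:**
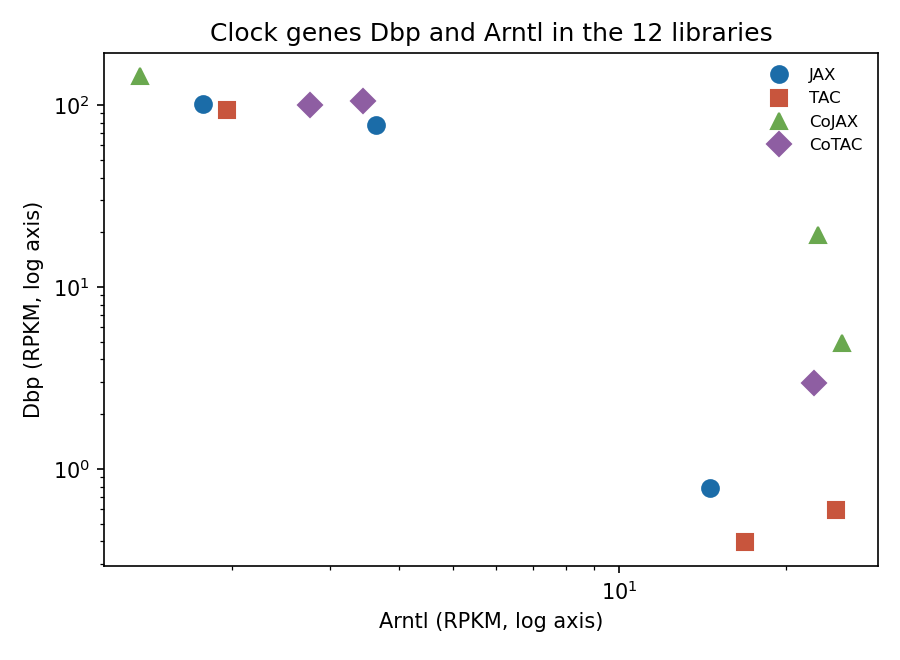
Dbp RPKM (vertical log axis) against Arntl RPKM (horizontal log axis) in each of the 12 libraries, marked by group. Within JAX, Dbp was listed at 77.5, 0.786 and 102 RPKM where Arntl was at 3.64, 14.6 and 1.77 RPKM.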

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

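The counts of other splits were planned before the results were seen, while the tests of the 3 patterns weighed below (differences of CoJAX from JAX, levels of abundant transcripts, clock genes) were chosen after. The vendor difference of 13 gene lists was called different between mice kept apart and mice kept together, by a camera test of the interaction. Higher and lower refer here to the signed Taconic minus Jackson difference and not to its size. With an estimated correlation these adjusted p-values were 0.377 to 0.671 and 0 lists were called, and 0 genes passed in the interaction. With the preset correlation it was higher apart for UGT and SULT conjugation (adjusted p = 5.14e-05), FMO and acyl-glycine conjugation (0.0156), bile acid synthesis (0.00618), hepatic transporters (0.00664), cholesterol synthesis (0.0156), lipogenesis (0.0183), gluconeogenesis and fasting (0.00671), endothelial markers (0.0183), male-biased liver genes (0.0153), periportal genes (0.00136), heat shock (0.00136) and the unfolded protein response (0.00419). It was lower apart for microbial sensing and cytokines (0.023). Outside the comparisons, of the 19 table lines named by a date number that could be tested, 2 passed between TAC and JAX, 6 between CoJAX and JAX, 1 between CoTAC and TAC and 3 in the vendor average, and the genes behind them were not identified.

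Other splits of the same libraries gave fewer genes in the pairs of groups. The real count and the highest of the other splits were 493 and 4 for TAC against JAX, 2911 and 2 for CoJAX against JAX, 78 and 1 for CoTAC against TAC, and 8 and 1 for CoTAC against CoJAX. In each case 1 of 10 splits, the real one, gave as many genes, and 10 splits are too few for a share under 0.05. For the vendor average 1 of 100 splits, the real one, gave as many as the real 418 genes, the highest other giving 119. The count thus stood above that of every other split drawn. A split that mixes the groups moves their difference, whatever its cause, into the spread within groups, which lowers its count. The low counts of the other splits therefore do not tell the vendor or housing from depth or handling. The splits also treat the libraries as exchangeable, so they cannot exclude chance differences between cages or animals, which the labels do not identify. For the interaction the real count is 0, which all 100 of 100 splits reach by definition, so they say nothing about it. The highest gave 418, since swapping the vendors in one housing turns the interaction into the vendor average.

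The difference of CoJAX from JAX in 24.1% of the genes is the first pattern weighed. Depth is a candidate explanation. With depth as a covariate the median difference of the 2911 called genes was 0.52 (0.47 to 0.61 without any 1 library) against 0.69, with a median SE of 0.19 against 0.17. This cannot decide, because the genes were chosen by the same difference without depth. Relative depth also did not overlap between the groups (at most 1 in JAX, at least 1.0882 in CoJAX). Depth therefore stays open. With depth in the fit 39 genes passed, at that smaller median and larger SE. A trend with transcript length and GC content is argued against as the whole cause, since 2454 genes passed after adjustment for it. The median of the 2911 called genes was then 0.57 (0.54 to 0.58 without any 1 library). Handling or RNA quality shared with TAC 1 stays open, since TAC 1 lay on the JAX side of TAC 2 and TAC 3 in 88.9% of these genes, by a median of 0.34, against 18.9% to 65% for the other libraries of Taconic mice. TAC 1 and the JAX libraries were also the shallowest, at relative depths of 0.7581 to 1 against at least 1.0541 elsewhere. The place of TAC 1 therefore cannot tell handling or RNA quality apart from depth. A response to cohousing stays open as well: the labels hold nothing that would separate it from handling, and depth, lower in every JAX library than in every CoJAX library, may account for an unknown part.

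The second pattern is the common level of abundant transcripts in each library. The RPKM of Alb had a CV of 30.9% over the libraries, against 3.92% for RPKM times depth. This does not decide whether true abundance was equal. A limit on the reads counted per position would spread RPKM with depth at equal abundance too. A candidate explanation is that reads starting at the same position were counted once, which caps a transcript at 2 reads per position over both strands. Within groups log2 Alb fell with log2 depth with a slope of -0.95, a Pearson r of -0.998 (exact permutation p = 0.000772), a Spearman rho of -1 (exact permutation p = 0.00154) and an r of -0.995 without the 2 libraries farthest from the median depth (1 relation tested). Small RNA genes such as Mir703 lay above this level, 14 of them at over 200% of Alb, and such a cap alone leaves them unexplained. Equal abundance could not be judged from these values, and no other biological explanation was tested.

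The third pattern is the spread of clock genes within every group. Between the 4 groups lay 8.52% of the variance of the clock score (one-sided permutation p = 0.862, 10000 permutations), which restates that spread, so a shift of the clock by vendor or housing stays open. A range test tried later (at least 6.71 within each group, 3.01 between group means) restates it too and was set aside. Collection at different clock phases stays open: in 10 of the 12 pairs of libraries within a group the one with more Dbp had less Arntl (exact permutation p = 0.0633), which misses the threshold. The pair test replaced a first one, a correlation of Dbp and Arntl pooled within groups, which passed the threshold (exact permutation p = 0.00309) and was set aside because Dbp falls into separate clusters of libraries. Collection times are not given in the labels.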

How the results depend on the processing

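Each alternative changed 1 choice, with these exceptions: the fit with both depth and the clock score, the correction near the upper level, which was then scaled by median ratios, the length and GC adjustment, which also left 11967 genes to test, and list tests in which another test and another setting were combined. The fits with depth, the clock score or both as covariates, the length and GC adjustment, the correction near the upper level and the fits without abundant genes, small RNA genes or 3 libraries were chosen after seeing the data. Leaving out each library gave 11 to 2113 genes for TAC against JAX, 1264 to 3431 for CoJAX against JAX, 2 to 1530 for CoTAC against TAC, 2 to 229 for CoTAC against CoJAX, 44 to 1905 for the vendor average and 0 to 46 for the interaction. With depth as a covariate these counts were, in the same order, 132, 39, 6, 5, 89 and 2, and with depth and the clock score 89, 27, 4, 2, 80 and 1. The clock score alone gave 905 genes for TAC against JAX and 655 for the vendor average. Without TAC 1, CoJAX 1 and CoJAX 2 the counts were 1793, 1121, 1, 1 and 198 for the first 5 comparisons. Array weights gave 2361 genes for TAC against JAX, 1047 for CoTAC against TAC, 50 for CoTAC against CoJAX, 2177 for the vendor average and 10 for the interaction. Fits of the compared groups alone gave 13, 1 and 1 genes for TAC against JAX, CoTAC against TAC and CoTAC against CoJAX. Without the trend the counts were 192 for TAC against JAX, 189 for the vendor average and 1 for the interaction, which had 3 genes without a filter. Quantile normalization gave 810 genes for TAC against JAX (492 higher, 318 lower). With the replicate number as a block 63, 2309, 17, 8 and 72 genes passed in the first 5 comparisons, and the numbers did not pair the libraries, whose deviations from the group means correlated at -0.174 to 0.151 between libraries of one number. The cause of these changes was not tested, apart from the fewer libraries of some fits. Other settings left the counts within 1.5 times. Of 61 list calls 1 held with an estimated correlation. Combined with that correlation, median-ratio scaling, quantile normalization, the replicate block, depth, and the length and GC adjustment each kept 0. The clock score kept 1 and the correction near the upper level kept 2. Quantile normalization kept 33 of the 61 in direction and call, as did the length and GC adjustment, and the balance of 14 higher and 47 lower calls became 36 and 22 or 25 and 26. Fry called 18 lists, 12 of them among the 61. Members past the threshold numbered 168 over all genes and 405 when adjusted over the lists alone. The 2 correlations between comparisons were 0.217 to 0.31 and 0.341 to 0.504 without 1 library. Among 151 named gene differences under 32 settings, 3971 results kept their side of the threshold and direction, 731 lost the call, 49 gained it and 2 reversed, the vendor averages of Cyp2e1 (0.064) and Cyp3a11 (0.03) under quantile normalization. At these depths a gene near 1 RPKM rests on a few reads, which limits what can be seen there.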

Other observations

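Acute phase genes differed between libraries of the same group. Lcn2, which encodes lipocalin 2, an iron-sequestering protein of the innate response to bacteria, was listed at 62.1, 227 and 100 RPKM in TAC 1, 2 and 3 and at 520, 19.0 and 537 RPKM in CoTAC 1, 2 and 3, against 13.4 to 27.4 RPKM in the 6 libraries of Jackson mice. Orm2, an acute phase glycoprotein gene, was listed at 324, 469 and 129 RPKM in TAC, at 339, 43.0 and 417 RPKM in CoTAC, at 79.0, 82.7 and 60.2 RPKM in JAX and at 75.6, 51.4 and 49.4 RPKM in CoJAX. Saa3, of a near-identical family, was listed at 442.5, 70.6 and 409 RPKM in CoTAC. Orm2 and Saa3 were chosen after their values were seen. The median of the 25 acute phase genes relative to the mean of all libraries was 0.40, 0.27 and -0.27 in TAC and 0.36, -0.53 and 0.43 in CoTAC. The acute phase list was called higher between CoTAC and CoJAX (camera adjusted p = 0.0216), and the call was lost at adjusted p = 0.665 with an estimated correlation. Between TAC and JAX its camera adjusted p was 0.187, in the interaction 0.935 and in the vendor average 0.0518, with 4 members higher when adjusted over the list alone.

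The same CoTAC libraries differed in markers of other liver cells. Endothelial markers had a median of -1, 0.02 and -1.39 in CoTAC 1, 2 and 3, against -0.08 to 0.66 in the other groups, and stellate cell markers had -0.71, -0.19 and -0.50. MHC class II genes had a median of 1.4 in JAX 1 and -1.33 in CoTAC 1. No explanation of these values was tested.

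The vendor differences apart and cohoused correlated with r = 0.274, and 2 of 100 splits of the libraries, the real one included, gave an absolute r as large, the highest other giving 0.287. For the cohousing changes in Jackson and Taconic mice (r = 0.462) it was 1 of 100, the highest other giving 0.412. The cohoused libraries were deeper on average in both vendors, and the Taconic libraries were deeper on average than the Jackson ones in both housings. These splits therefore separate neither cohousing nor vendor from depth. With depth as a covariate r was 0.252 for the vendor differences and 0.489 for the cohousing changes.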
